A study of Mus musculus with 2 samples.

How the data were processed

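Total RNA depleted of ribosomal RNA was measured by stranded paired-end sequencing in 2 libraries of newborn mouse forebrain, with RNA spike-ins added, per the labels. Both libraries form 1 group, forebrain at birth, and no comparison between conditions exists in the design. The authors deposited gene and transcript quantifications of each library on the mm10 assembly and GENCODE M4 annotation, made from alignments of that library alone, according to the text supplied with each sample. The aligner and the quantifier are not given in the sources used here, although the column names are those that RSEM writes. The deposited tables hold expected counts, which are not whole where features share reads, posterior mean counts and the posterior standard deviation of each count. The deposited TPM values sum to the same total in each library over all features, spike-ins and short noncoding RNAs included. The deposited FPKM values are scaled by effective length and by the number of fragments. The deposited isoform percentages give the share of a gene's TPM held by each transcript, per the file headers. Deposited interval bounds of TPM were used for the ratios of subunit pairs, and the FPKM bounds were not used here.

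Of 43346 genes in the deposited tables, 42462 (98%) were matched by identifier to GENCODE M21, which uses the same assembly and gave symbols, biotypes and coordinates. The unmatched genes held 0.15 and 0.138% of counts. The 26248 tRNA entries, all at 0, and the spike-ins were left out of the gene counts. The list members Rmst, Sox2ot, Ca9 and Kiss1 had no match and were left out. Mean fragment lengths implied by the effective lengths were 249 and 269.7 nt. Totals were 62516003 and 65912060 expected counts, and a count of 0 was taken to allow up to 3 counts. Shares of counts carry 95% Wilson intervals. Coding TPM is TPM rescaled to the full TPM total over protein-coding genes, by factors of 7.38 and 4.54, and was chosen after seeing the data.

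Expected counts were rounded to whole numbers. TMM factors and the common dispersion came from edgeR 4.0.16 with an intercept-only design, over genes with a mean of at least 10 counts, and DESeq2 1.42.0 supplied alternative size factors, in R 4.3.3. Differences between the libraries were tested by a two-sided exact binomial test per gene with Benjamini-Hochberg adjustment over 17544 genes, and called at an adjusted p under 0.05 and at least 2-fold. Ratios had 0.5 added to each count. The test compares the reads of these libraries only, since with n = 2 libraries in 1 group no test between conditions can be made. For each of 36 lists of marker genes or gene classes, the median log2 ratio of members past the count filter was set against 10000 random lists of the same size matched on expression in 20 bins, and called outside the central 95%. Lists needed at least 3 such members, which 32 had. Regional identity was the difference of median log2(TPM + 0.1) between telencephalic factors and midbrain, hindbrain and Hox genes. Further comparisons took TPM within subunit pairs and the dominant transcripts of 16 genes. The length and GC trend was a spline with 5 degrees of freedom fitted on 13568 genes with a mean of at least 100 counts, using the GC content of each gene's main transcript, and covered 17345 of the genes tested. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 served the other steps.

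The groups, lists, tests, naming rule and most alternatives were fixed before the data were examined. Named genes were, per list, the 3 members with the highest mean TPM and the lowest, and of each shifted list the 4 members with the largest ratio in its direction. Also named were the 15 protein-coding and 10 other genes with the highest TPM, the 10 highest and 10 lowest ratios among called genes with a mean of at least 100 counts, and the genes of the pairs and isoforms, with the spike-ins given as a summary. Some genes and pairs that meet these rules are not reported here. Alternatives were other TPM thresholds (0.5 and 5), FPKM, other TPM denominators, DESeq2 size factors, library totals, no filter, a filter of 100 counts, posterior mean counts, an error with the posterior SD, a 1.5-fold threshold, library sizes without mitochondrial and the 10 most abundant genes, pseudocounts of 1 and 0.01, unmatched random lists, lists without their extreme member, transcripts of at least 500 nt, and leaving out each replicate. Protein-coding genes alone, coding TPM and removal of the length and GC trend were added after seeing the data. The spike-in slope over length was tested with 100000 permutations, and the rho over length has an interval from 1000 bootstrap samples of genes. Lists of hypothalamic, osteoblast, leptomeningeal and midbrain dopamine genes were chosen after the extreme ratios were seen, without the called genes that prompted them. The steps were tested on simulated data. In a set with a coefficient of variation of 0.20 and no changed genes, 0.201 was estimated. In a separate set with counting noise alone, 100 of 100 genes changed 3-fold were recovered with 0 false calls. The changed genes were drawn only from genes well above the count filter, so recovery of genes with few counts was not tested. That separate set also lacks the variation between real isolates, so it does not show how many calls such variation gives. Of 100 unshifted lists 5 were called. Sequence reads were not used here.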

Results

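Total RNA was sequenced from forebrain of newborn mice (age 0 days, strain B6NTac;B6NCrl/Lap, both sexes pooled) in 2 rRNA-depleted, stranded libraries. The labels call them biological replicates 1 and 2, made from separate tissue isolates, the first from 15 mice and the second from a pool whose size is not given here. The sample labels also give both the same donor identifier, so SDs and the coefficient of variation describe the spread between these isolates only. The libraries form 1 group, forebrain at birth (n = 2 libraries), so the comparisons are between genes within the tissue and between the isolates. Replicate 1 held 62516003 expected counts and replicate 2 held 65912060. A count of 0 allowed up to 3 counts of these totals. These floors and the binomial intervals given here cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Each ± is an SD over the n = 2 libraries, and genes are not replicates.

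By TPM, the most abundant transcripts of newborn forebrain came from short structural RNAs transcribed by RNA polymerase III. Rn7s1 (300 nt) and Rn7sk (331 nt) are little longer than the mean fragments of 249 and 269.7 nt. Their TPM therefore rests on short effective lengths and is uncertain as a measure of abundance. By counts, the mitochondrial ribosomal RNAs exceeded these genes in both libraries. The 7SL RNA genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, and Rn7sk, which encodes a regulator of transcription elongation, together held 68.9 ± 5.87% of TPM. Their share of counts was 11.3% (95% Wilson interval 11.25 to 11.26%) in replicate 1 and 4.36% (95% Wilson interval 4.353 to 4.363%) in replicate 2. Rn7s1 stood at 288448 and 248207 TPM and Rn7sk at 155936 and 150703 TPM in replicates 1 and 2. Rn7s1 and Rn7s2 share nearly all their sequence, so the division of reads between these copies is uncertain. Rpph1, the RNA of RNase P, had 24734 and 26586 TPM, and Rmrp, the RNA of RNase MRP, had 39635 and 9129 TPM. The mitochondrial ribosomal RNAs took 14.5 ± 0.16% of counts, most of it mt-Rnr2 at 38477 and 59971 TPM, while mt-Rnr1 had 7274 and 12072 TPM. The small Cajal body RNA Scarna10 reached 4945 and 2513 TPM. Gm26917, annotated as a long intergenic noncoding RNA, was listed at 1022 and 1418 TPM, and the origin of its reads was not tested. Gm28661, a nuclear pseudogene copy of mitochondrial sequence, was listed at 788 and 368 TPM, and its reads cannot be assigned with certainty. Protein-coding genes held 73.4 ± 5.73% of counts and 17.8 ± 6.0% of TPM. Levels of genes are therefore given as coding TPM, that is TPM rescaled to a common sum over protein-coding genes, a unit chosen after these shares were seen.

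Among protein-coding genes, several of the highest encode the cytoskeleton of growing neurons. Tuba1a (ENSMUSG00000072235.5, mm10 chromosome 15, 98949837 to 98953703), an alpha-tubulin of young neurons, was highest at 22271 ± 2136 coding TPM. Beta-tubulin genes were also among the 15 highest, with Tubb2b at 6322 ± 104, Tubb2a at 4286 ± 41.7, the neuronal Tubb3 at 3734 ± 104 and Tubb5 at 3588 ± 31.7. Actb, a cytoplasmic actin, stood at 5332 ± 282, and Eef1a1 (chromosome 9, 78478449 to 78489151), a translation elongation factor, at 10194 ± 1737. Nnat (chromosome 2, 157560078 to 157562522), an imprinted proteolipid gene of developing brain, had 5757 ± 1794. The mitochondrially encoded cytochrome oxidase subunits mt-Co1, mt-Co3 and mt-Co2 had 13744 ± 769.9, 11789 ± 87.1 and 4318 ± 1229. In replicate 1 the posterior SD was 22194 for the 139504 counts of mt-Co3 and 10985 for the 33024 of mt-Co2. The assignment of their reads is thus uncertain beyond the SDs over libraries. Hist1h4c and Hist1h4d, which encode histone H4, had 3689.9 ± 349 and 3095 ± 2226, and the chaperone gene Hspa8 and ribosomal Rplp1 completed the 15 highest at 3687 ± 622 and 3513 ± 429.6. In all, 11151 of 43346 genes reached 1 TPM in both libraries, 11209 in replicate 1 and 12734 in replicate 2. At 1 coding TPM the number was 14936.

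Transcription factors of the telencephalon were expressed and those of the hindbrain and spinal cord were near or at 0, a comparison of regional identity within the dissected tissue. All 16 telencephalic factors reached 1 coding TPM in both libraries, with a median of 22.2 ± 5.17. Lhx2, a selector of cortical fate, had 82.2 ± 3.69, Dlx1, a factor of GABAergic neurons, 74.2 ± 5.03, and the lowest was Gsx2, a progenitor factor of the lateral ganglionic eminence, at 1.31 ± 0.125. The 10 diencephalic factors had a median of 3.1 ± 2.39, led by Lhx9 (24.2 ± 8.07), Tcf7l2 (13.7 ± 4.73) and Gbx2 (11.3 ± 3.41), all genes of the developing thalamus, and the lowest was the hypothalamic Hmx3 (0.979 ± 0.863). Of 12 midbrain and hindbrain factors 2 reached 1 coding TPM in both libraries, and their median was 0.207 ± 0.229. The highest were Gata2 (1.88 ± 0.878), Egr2 (1.82 ± 0.772) and Lmx1b (1.26 ± 1.05). Hox genes, which pattern the hindbrain and spinal cord, had 0 counts in both libraries for 14 of 16 members, Hoxa4 and Hoxd4 among them. Hoxa3 had 10 and 0 counts and Hoxd8 1 and 3 in replicates 1 and 2. The median log2(TPM + 0.1) of telencephalic factors exceeded that of the 28 midbrain, hindbrain and Hox genes by 5.28 ± 0.81, with 4.71 in replicate 1 and 5.86 in replicate 2. Its size follows the pseudocount, because most members of the second set were at or near 0, and only 3 of them averaged at least 0.1 TPM. With those members alone the difference was 3.35, and with a pseudocount of 1 TPM it was 2.28.

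**Figure D1:**
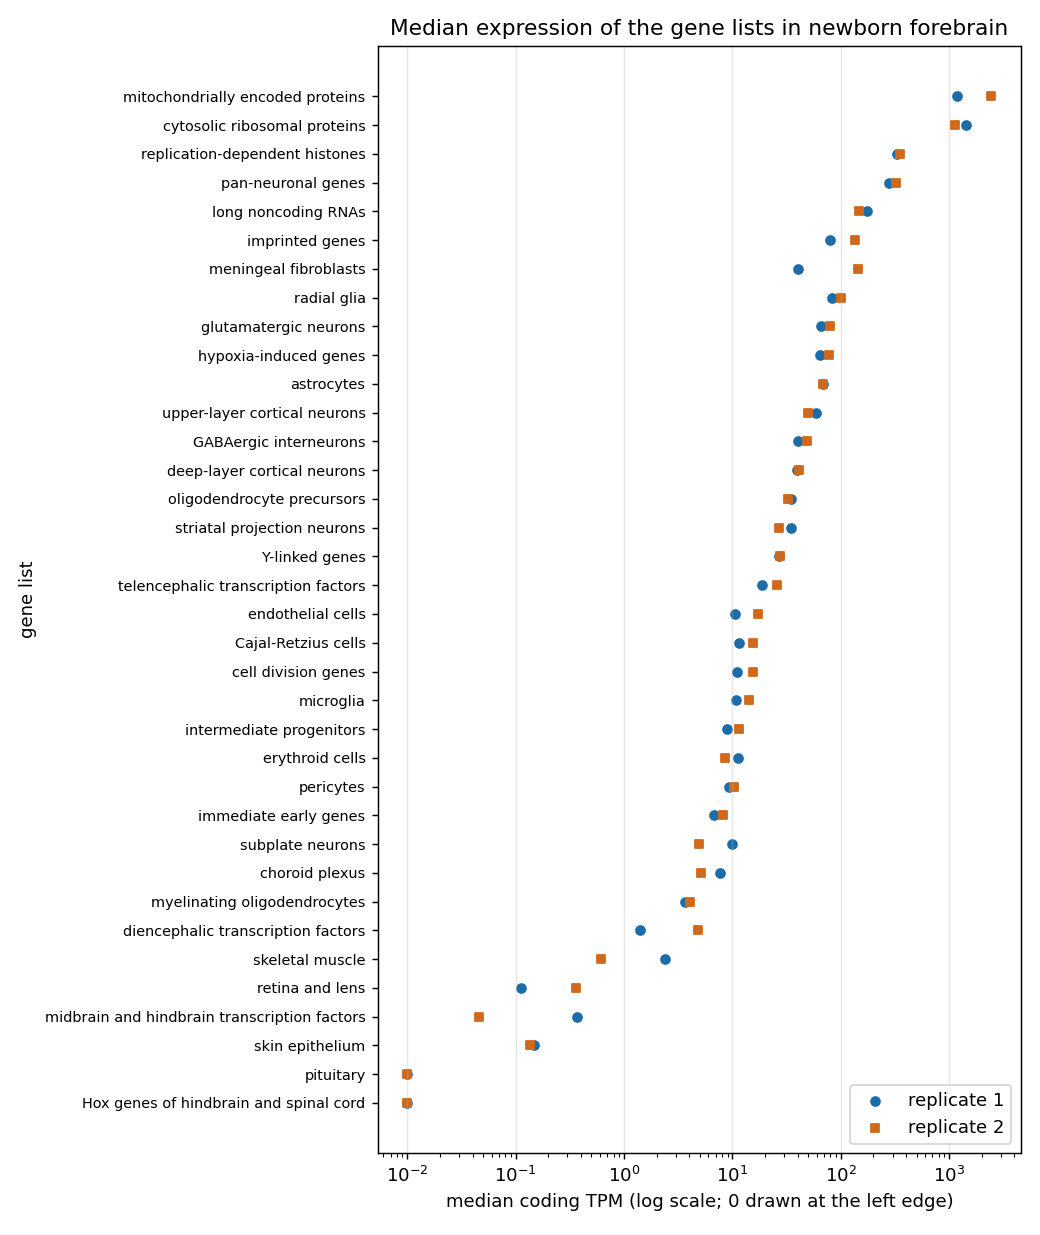
Median coding TPM of each gene list fixed before the data were examined, on a log axis, with points for replicates 1 and 2 and medians of 0 drawn at the left edge. Mitochondrial, ribosomal, histone and pan-neuronal genes lie at the top of the range and Hox and pituitary genes at 0.

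Neuronal genes of every class examined were present. The 12 pan-neuronal genes had a median of 300.3 ± 27.9 coding TPM, with Map2, a dendritic microtubule protein, at 1202 ± 39, Gap43, of growing axons, at 1112 ± 59.6, and the neurofilament gene Nefm lowest at 12.4 ± 3.56. Glutamatergic genes had a median of 72.9 ± 9.9, led by the AMPA receptor subunit Gria2 (285 ± 17.1) and the factors Neurod6 (212 ± 43) and Neurod2 (132 ± 5.82), with Neurod1 lowest (14.5 ± 1.11). GABAergic interneuron genes had a median of 44.7 ± 5.79, led by the neuropeptide genes Sst (289.7 ± 12.8) and Npy (238 ± 53.9) and by Gad1 (111 ± 26.8), which makes GABA, with the serotonin receptor Htr3a lowest (8.17 ± 0.25). Upper-layer cortical genes had a median of 54.6 ± 7.11, with Mef2c at 233 ± 92.6, Cux1 at 128 ± 11.1, Pou3f3 at 76.4 ± 2.66 and Inhba, a subunit of activin, lowest at 2.26 ± 1.4. Deep-layer genes had a median of 40.5 ± 1.46, with Crym at 134 ± 8.83, Bcl11b, a factor of corticospinal neurons, at 109 ± 12.5, Tle4 at 72.7 ± 8.48 and Zfpm2 at 9.52 ± 2.71. Striatal projection neuron genes, all 12 at 1 TPM or more in both libraries, had a median of 30.9 ± 5.79, with Meis2 at 209 ± 17.8, Foxp1 at 131 ± 32.1, the neuropeptide precursor Tac1 at 62.3 ± 8.87 and the dopamine receptor Drd2 at 8.96 ± 1.43. Subplate genes had a median of 7.4 ± 3.53, from Nr4a2 (27.5 ± 2.96), Ccn2 (15.6 ± 3.43) and Moxd1 (7.4 ± 3.53) down to Cplx3 (0.542 ± 0.382). Cajal-Retzius genes had a median of 13.5 ± 2.65, from Reln, which guides cortical layering (165 ± 45.2), Calb2 (128 ± 0.408) and Ndnf (20.8 ± 3.23) down to Trp73 (2.95 ± 1.15).

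Genes of progenitors and precursor glia were expressed beside low levels of myelin genes. Radial glial genes had a median of 91.4 ± 12.4 coding TPM, led by the fatty acid binding protein gene Fabp7 (1210.5 ± 113), the intermediate filament gene Vim (479 ± 74.4) and the glutamate transporter Slc1a3 (214 ± 14.8), with Hes1 lowest (8.76 ± 2.96). Intermediate progenitor genes had a median of 10.1 ± 1.81, with Insm1 at 23 ± 9.42, Gadd45g at 13.4 ± 0.0194, Btg2 at 10.2 ± 1.82 and Neurog1 with 3 and 0 counts. Cell division genes had a median of 13.3 ± 3.21, with Pcna, of DNA replication, at 141 ± 7.27, Cdk1, the mitotic kinase, at 43.3 ± 3.23, Top2a at 34.2 ± 7.03 and Bub1 at 4.44 ± 0.848. Astrocyte genes had a median of 68.3 ± 0.249, led by Apoe, a lipid carrier (1219.9 ± 226), Sparcl1 (290.0 ± 3.06) and Aldoc (190.5 ± 14.7), with S100b at 3.44 ± 0.564. Oligodendrocyte precursor genes had a median of 33.7 ± 1.34, with the factors Olig1 (113 ± 18.6), Olig2 (37.1 ± 6.15) and Sox10 (7.45 ± 0.844) and the growth factor receptor Pdgfra (38.1 ± 4.95). Genes of myelinating oligodendrocytes had a lower median of 3.86 ± 0.289, with Cldn11 at 38.9 ± 15.2, Cnp at 38 ± 2.6 and 0 counts of Mog in both libraries. Microglial genes had a median of 12.5 ± 2.28, led by the complement genes C1qc (61 ± 1.52), C1qb (53.6 ± 1.81) and C1qa (48.6 ± 3.43), with Aif1 at 2.66 ± 1.25.

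Genes typical of vessels, blood, choroid plexus and meninges were also detected. Endothelial genes had a median of 13.9 ± 4.76 coding TPM, led by the tight junction gene Cldn5 (161 ± 19), Esam (36 ± 11.2) and Pecam1 (17.8 ± 5.38), with the angiopoietin receptor Tek at 8.43 ± 2.21. Pericyte genes had a median of 9.79 ± 0.793, with Rgs5 at 66.3 ± 13.7, Pdgfrb at 15.8 ± 6.45, Kcnj8 at 9.79 ± 0.793 and Anpep at 3.25 ± 0.102. Of the hemoglobin genes, Hba-a2 had 841 ± 116, Hbb-bs 673 ± 175 and Hba-a1 468 ± 110.1, whereas the embryonic Hbb-bh1 had 0 counts, and the erythroid median was 9.84 ± 1.85. The alpha-globin copies are near-identical, so the division of reads between them is uncertain. Choroid plexus genes had a median of 6.37 ± 1.75, with Ttr, the thyroid hormone carrier, at 579.6 ± 188, Otx2 at 12.6 ± 1.92, Aqp1 at 11.2 ± 1.78 and Kl at 1.44 ± 0.0491. Meningeal fibroblast genes had a median of 91.4 ± 72.8, with the growth factor gene Igf2 at 212 ± 91.4, the collagen genes Col1a2 at 152 ± 129 and Col1a1 at 98.1 ± 102, and Lum at 9.47 ± 5.87. Genes of neighbouring tissues were low, with medians of 0.237 ± 0.178 for retina and lens, 0.142 ± 0.00812 for skin, 1.49 ± 1.24 for skeletal muscle and 0 for pituitary. Their highest members were the photoreceptor factor Crx (1.53 ± 0.555), the keratin gene Krt1 (7.15 ± 0.225), the actin gene Acta1 (14.6 ± 6.23) and the hormone precursor Pomc (4.65 ± 1.77). Rcvrn had 0 and 18 counts, Krt10 1.67 ± 0.246 coding TPM, Krt14 0.142 ± 0.00812, Ckm 2.79 ± 2.53, Tnnt3 1.39 ± 0.288 and Myh3 0.372 ± 0.205. Cga and Pou1f1 each had 1 and 0 counts in replicates 1 and 2, and Lhb, Crybb2 and Krt15 had 0 in both.

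Other classes of genes ranged from the highest levels of the tissue to low ones. The Y-linked genes were at similar levels in both mixed-sex pools, with Eif2s3y at 54.5 ± 1.83, Ddx3y at 32.1 ± 1.77, Uty at 21.8 ± 1.26 and Kdm5d at 21.3 ± 0.15 coding TPM and a median of 27 ± 0.366. Immediate early genes, which respond to stimulation, had a median of 7.48 ± 0.975, with Dusp1 at 35.6 ± 5.53, Junb at 21 ± 0.431, Fos at 15.5 ± 2.55 and Fosb at 1.55 ± 0.83. Imprinted genes had a median of 106 ± 39, with Ndn at 1009 ± 292, the noncoding Meg3 at 926 ± 175, Snrpn at 385 ± 3.27 and Kcnq1ot1 at 3.28 ± 0.247. Long noncoding RNAs had a median of 162 ± 19, led by Rian (2276 ± 258) and Malat1 (2013 ± 115), with Neat1 lowest (3.05 ± 1.28). Hypoxia-induced genes had a median of 71 ± 10.4, with the glycolytic Ldha (379 ± 29.3) and Pgk1 (218 ± 1.83), Bnip3 (139.9 ± 1.07) and Adm (1.92 ± 0.107). Ribosomal protein genes had a median of 1289 ± 214, with Rpl10 at 2047 ± 102, Rplp0 at 1858 ± 189 and Rpl5 at 193 ± 6.56. Replication-dependent histone genes had a median of 339.7 ± 13.7, with Hist1h1c at 469 ± 18.6, Hist2h2ac at 461 ± 11.6 and Hist1h1a at 79.1 ± 13.6. The mitochondrially encoded protein genes had a median of 1818 ± 887, and mt-Atp8 was listed at 0 TPM despite 833 and 350 counts, its annotated length being under the mean fragment length implied by the tables.

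Subunits typical of immature neurons were compared with their later partners within each library, as a measure of neuronal maturity, and the early partner was higher for the NMDA receptor, glycine receptor and sodium channel subunits. The NMDA receptor subunit Grin2b stood at 70.7 ± 7.79 coding TPM against 7.55 ± 0.754 for Grin2a, with TPM ratios of 9.29 and 9.43. The sodium channel gene Scn2a exceeded Scn1a by ratios of 7.55 and 9.01, and Scn3a exceeded Scn8a by ratios of 5.46 and 5.91. The glycine receptor subunit Glra2 stood at 100.3 ± 5.11, and Glra1 had 0 counts in replicate 1 and 10 in replicate 2, where the TPM ratio was 572 (deposited TPM bounds give 244 to 808). The order was opposite for Slc12a2, which imports chloride, against the exporter gene Slc12a5, with ratios of 0.256 and 0.20 and levels of 28.4 ± 6.01 and 129 ± 48.9. It was also opposite for the scaffold genes Dlg3 and Dlg4, with ratios of 0.183 and 0.184.

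**Figure D2:**
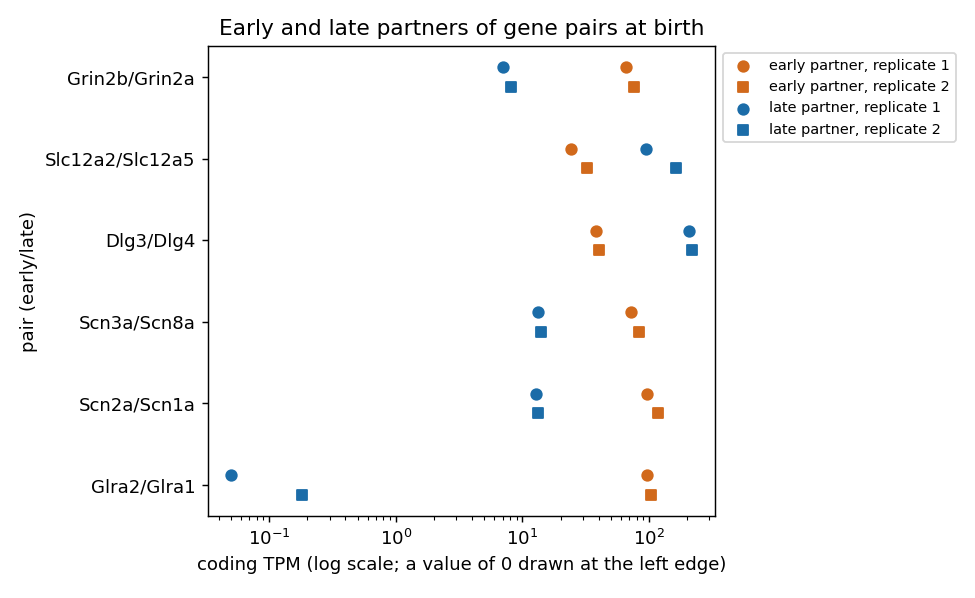
Coding TPM of the early and the late partner of gene pairs on a log axis, with circles for replicate 1 and squares for replicate 2, and a value of 0 drawn at the left edge. The late partner is higher in both libraries for Slc12a2/Slc12a5 and Dlg3/Dlg4, and the early partner for the other pairs plotted.

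All 16 neural genes examined for splicing had the same dominant transcript in both libraries, and it was annotated as protein-coding for 15. The leading Ank2 transcript had no match in GENCODE M21, so its type was not available. For the microtubule gene Mapt, transcript Mapt-204, of 10 exons, held 97.7 ± 0.728% of the gene's TPM. The synaptic gene Snap25 gave 62.7 ± 0.0212% to Snap25-201 and 36.6 ± 0.141% to Snap25-202. Cdc42, a small GTPase with alternative last exons, divided into 54.5 ± 1.55% Cdc42-201 and 45.5 ± 1.55% Cdc42-202. Tpm3-201 held 66.2 ± 0.764%, Mef2c-202 67.7 ± 3.46%, Clta-204 65.2 ± 6.89%, Dab1-203 65 ± 1.34%, Dlg4-201 81.1 ± 7.04% and Bin1-201 91.6 ± 5.74%. The shares were more divided for Camk2b-209 (48.4 ± 4.46%), Gria2-202 (28.4 ± 6.25%), Map2-201 (27.9 ± 0.70%) and the leading Ank2 transcript (25.4 ± 1.24%). In replicate 2 Gria2-202 only narrowly exceeded Gria2-204, annotated as a retained intron, at 23.97 against 23.45%. Numb-204 held 52.2 ± 5.78%, and the second transcript, Numb-206 of 429 nt, held 2.02% in replicate 1 and 37.8% in replicate 2. Ptbp2 had 1 transcript in the annotation, so its agreement between the libraries was certain and its 100% share carries no information on splicing. Short reads give only estimates of these shares, and 10 of the 16 dominant transcripts held most of the gene's TPM in both libraries.

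The isolates differed in the lists of diencephalic, meningeal fibroblast and muscle genes, among other groups. An osteoblast list chosen after the extreme ratios were seen was higher in replicate 2 too, so the meningeal list need not speak for meninges alone. Ratios are log2 of replicate 2 over replicate 1 after TMM scaling, with the standard error from counting and the deposited posterior SD, and they compare these libraries, not conditions. The 10 diencephalic factors had a median of 1.11 (percentile 100, central range of matched random lists -0.39 to 0.40), and 5 of them passed the test, all higher in replicate 2. These were Rax (2.72, SE 0.58), Hmx3 (1.84, SE 0.50), Otp (1.77, SE 0.21), Sim1 (1.55, SE 0.10) and Irx3 (1.36, SE 0.24), while the other ratios lay above 0 and under 2-fold, the lowest that of Hmx2 (0.38, SE 0.33). Rax (7 and 59 counts) and Hmx3 (10 and 45) had few reads, and the 6 members that averaged 100 counts or more, which leave both out, had a median of 0.70, still above the range of random lists. Meningeal fibroblast genes had a median of 0.85 (percentile 100, central range of matched random lists -0.26 to 0.20) and ratios above 0 for all 7 members, and the collagens Col1a1 (2.57, SE 0.027), Col1a2 (1.79, SE 0.020) and the proteoglycan Lum (1.19, SE 0.12) passed the test, while Igf2 (0.85, SE 0.023) was under 2-fold. Skeletal muscle genes had a median of -1.93 (percentile 0.040, central range of matched random lists -0.90 to 1.08), with 5 of 6 members past the test as lower. The remaining member, Tnnt3, had a ratio above 0 and did not pass the test. The muscle creatine kinase gene Ckm had a ratio of -2.33 (SE 0.30), Acta1 of -1.07 (SE 0.11) and Myh3 of -1.53 (SE 0.32), Myl1 went from 36 counts to 0 (at least 14.6-fold lower), and Tnni2 from 19 to 3. Too few members averaged 100 counts for the list to be tested at that level.

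Of the 32 gene lists with enough counts, 15 lay outside the central 95% of matched random lists, 7 of them higher and 8 lower in replicate 2. Chance would place 1.6 there if genes and lists were independent. Markers of a tissue can vary together and some lists share members, so 1.6 is too low a standard for these lists. Telencephalic factors had a median of 0.34 (range of matched random lists -0.22 to 0.20), with Six3 (1.72, SE 0.13) and the ventral forebrain factor Nkx2-1 (1.502, SE 0.14) past the test, both expressed in hypothalamus as well as telencephalon, and Dlx5 (0.79, SE 0.14) and Pax6 (0.78, SE 0.064) under 2-fold. The list did not move one way, as 5 of 16 members had ratios under 0, among them the cortical Emx1 (-0.84, SE 0.069), Otx1 (-0.76, SE 0.14) and Lhx2 (-0.34, SE 0.036). Imprinted genes had a median of 0.47 (range of matched random lists -0.19 to 0.14), with the growth regulators Plagl1 (0.98, SE 0.055), Igf2 (0.85, SE 0.023), Dlk1 (0.76, SE 0.083) and H19 (0.68, SE 0.024) highest but none at 2-fold, and Igf2 belongs to the meningeal list as well. Endothelial genes had a median of 0.37 (range of matched random lists -0.30 to 0.25), with Cdh5 (0.56, SE 0.061), Tie1 (0.39, SE 0.065), Tek (0.39, SE 0.073) and Esam (0.37, SE 0.060) highest. GABAergic genes had one of 0.24 (range of matched random lists -0.20 to 0.17), with Nr2f2 (0.73, SE 0.047), Slc32a1 (0.50, SE 0.051), Gad2 (0.43, SE 0.029) and Gad1 (0.33, SE 0.025) highest. Of the 11 GABAergic members 7 had ratios above 0 and 4 under 0. The lower ones were Npy (-0.71, SE 0.050), Maf (-0.33, SE 0.047), Htr3a (-0.23, SE 0.11) and Sst (-0.15, SE 0.043). No member of either list reached 2-fold. Long noncoding RNAs had a median of 0.16 (range of matched random lists -0.20 to 0.14), with Neat1 (0.98, SE 0.076), Xist (0.50, SE 0.018), Meg3 (0.47, SE 0.010) and Malat1 (0.34, SE 0.0053) highest but under 2-fold, while the only member past the test, Pantr1 (-1.42, SE 0.061), was lower, and Meg3 belongs to the imprinted list as well. On the lower side, erythroid genes had a median of -0.73 (range of matched random lists -0.30 to 0.28), or -0.43 with the length and GC trend removed. Slc4a1 (-2.38, SE 0.32) and Hbb-bt (-1.37, SE 0.058) passed the test, and Hbb-bs (-0.74, SE 0.024) and Hba-a1 (-0.71, SE 0.042) were under 2-fold. Midbrain and hindbrain factors had a median of -0.89 (range of matched random lists -0.81 to 0.98), with En2 (-3.16, SE 0.76), En1 (-1.86, SE 0.43) and Pax7 (-1.67, SE 0.60) lower, Egr2 (-0.89, SE 0.21) under 2-fold and Lmx1b (1.85, SE 0.23) higher. The median of the 7 members tested was the ratio of Egr2 itself. Gata3 (-0.48, SE 0.34) was lower but inside the range, and Gata2 (0.86, SE 0.19) was higher. With members of at least 100 counts on average alone, 3 members gave a median of the opposite sign, 0.87, inside the range of random lists. Ribosomal protein genes had a median of -0.56 (range of matched random lists -0.16 to 0.12), or -0.20 with the length and GC trend removed, and ratios under 0 for all 12 members but none at 2-fold, Rps18 (-0.90, SE 0.020), Rps3 (-0.79, SE 0.015) and Rpl7 (-0.68, SE 0.014) lowest. Striatal genes had a median of -0.51 (range of matched random lists -0.21 to 0.18), with the dopamine receptor Drd1 (-0.98, SE 0.068), the signalling regulator Ppp1r1b (-0.94, SE 0.069) and the adenosine receptor Adora2a (-0.58, SE 0.069), all under 2-fold. Upper-layer genes had a median of -0.37 (range of matched random lists -0.22 to 0.18), with Inhba (-1.54, SE 0.28) past the test and Mef2c (-0.95, SE 0.013) and Rorb (-0.44, SE 0.035) under 2-fold. Choroid plexus genes had a median of -0.38 (range of matched random lists -0.34 to 0.39), with the potassium channel subunit Kcne2 (-1.60, SE 0.25) past the test and Ttr (-0.85, SE 0.018), Clic6 (-0.82, SE 0.11) and Folr1 (-0.51, SE 0.16) under 2-fold, and oligodendrocyte precursor genes one of -0.39 (range of matched random lists -0.31 to 0.26), with Olig1 (-0.50, SE 0.029), Olig2 (-0.50, SE 0.048), Sox10 (-0.39, SE 0.10) and Pdgfra (0.11, SE 0.028), none at 2-fold. Without the member of largest ratio, the choroid plexus median was -0.26, the precursor median -0.14 and the midbrain and hindbrain median -0.68, all 3 inside the range of random lists, and the choroid plexus list also fell inside it at 100 counts. Against random lists not matched on expression, the GABAergic, endothelial, precursor and long noncoding lists fell inside the range. The other 17 lists tested, with deep-layer, pan-neuronal, glutamatergic, radial glial, microglial and Y-linked genes among them, stayed inside the range in the main comparison. Among members of the lists tested, 31 differed at least 2-fold when adjusted over the list alone, and 31 when adjusted over all genes tested. Of all 17544 genes tested, 1808 differed in this way, a similar share, so these counts do not set the list members apart.

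**Figure D3:**
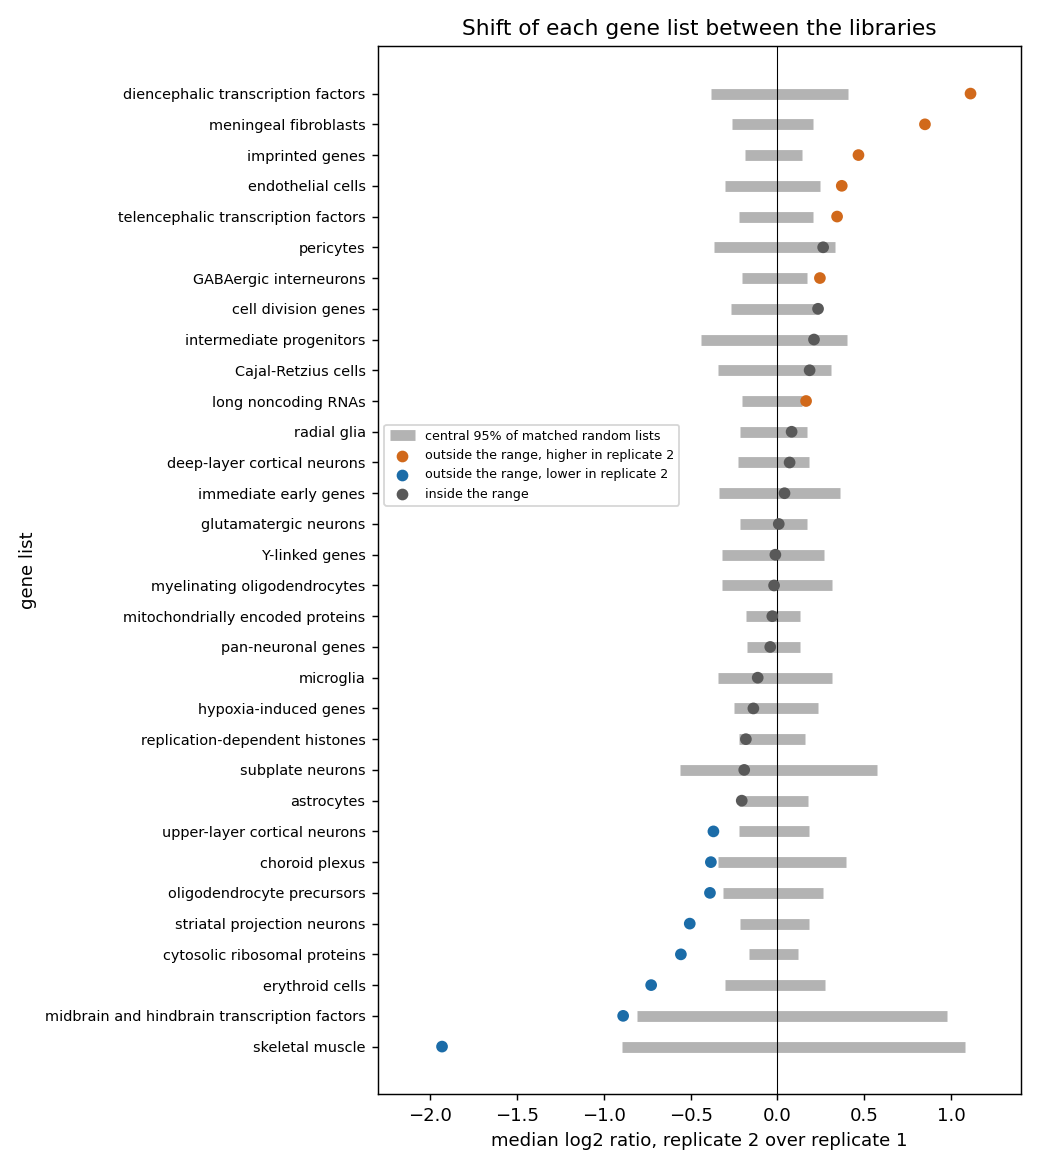
Median log2 ratio (replicate 2 over replicate 1) of each list, with grey bars for the central 95% of random lists matched on expression. Diencephalic and meningeal lists lie farthest right at 1.11 and 0.85, and skeletal muscle farthest left at -1.93.

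The 10 highest and 10 lowest ratios, among genes past the test with a mean of at least 100 counts, belonged to genes of several kinds. Rmrp was lower in replicate 2, with a ratio of -3.92 (SE 0.013), as was the small Cajal body RNA Gm25395 at -4.77 (SE 0.34). Tnn (3.33, SE 0.29) and Ibsp (2.77, SE 0.15) were higher in replicate 2, as was Efhb (2.59, SE 0.29), and Sspo (-2.87, SE 0.29), the large glycoprotein of the subcommissural organ, was lower. The protein-coding Gm11232 went from 0 counts to 217 (at least 59.6-fold higher). The pseudogene Gm10231 and the unmatched ENSMUSG00000102226.1 and ENSMUSG00000103627.1 had 0 counts in replicate 1 and 203, 363 and 220.5 in replicate 2, but their posterior SDs in replicate 1 were 11.7, 20.7 and 9.47 counts, so no fold is given. The pseudogenes Gm10359 (-8.27, SE 64.90), Gm29216 (-5.73, SE 0.30), Gm4149 (-3.13, SE 0.29) and Gm10222 (-2.93, SE 0.65) were lower, and Gm7336 (3.44, SE 5.03), Zxda (3.10, SE 2.02) and Gm15421 (3.07, SE 0.79) were higher. The ribosomal protein copy Rps27rt (-2.89, SE 0.14), Gm27029 (-2.63, SE 0.38) and the unmatched ENSMUSG00000091964.3 (-2.89, SE 5.10) completed the 10 lowest. Pseudogenes and multicopy genes share reads with their relatives, and 5 of the 10 lowest and 6 of the 10 highest had a posterior SD of at least 5% of the count and are uncertain. With the deposited posterior SD in the error, Gm10359, Gm7336, Zxda, Gm10231 and the 3 unmatched genes named here no longer passed the test.

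Genes with a mean of at least 10 counts numbered 17544, and 1808 of them differed beyond counting noise and at least 2-fold, 952 higher and 856 lower in replicate 2. Protein-coding genes made up 1099 of these, out of 15187 tested, against 709 of 2357 other genes. The higher genes were 52.7% of those called, but 66.8% with library totals, which moved the median of all genes by 0.20 log2, and 62.9% with the trend over length and GC content removed, an alternative chosen after seeing the data. At this depth counting noise is small, and 11395 genes passed the adjusted exact test alone. The ratios followed transcript length, with medians of -0.53 for genes of 300 to 500 nt, -0.19 for 1000 to 1500 nt, -0.01 for 2000 to 3000 nt and 0.15 above 5000 nt. The 41 genes up to 300 nt had a median of -0.32. The ribosomal protein, erythroid and histone lists have short transcripts, with median lengths of 1068, 703 and 631 nt, and with the trend removed their medians were -0.20, -0.43 and 0.32. All 15 shifted lists stayed outside the random range with the trend removed, and the histone, mitochondrial and cell division lists lay above it as well.

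**Figure D4:**
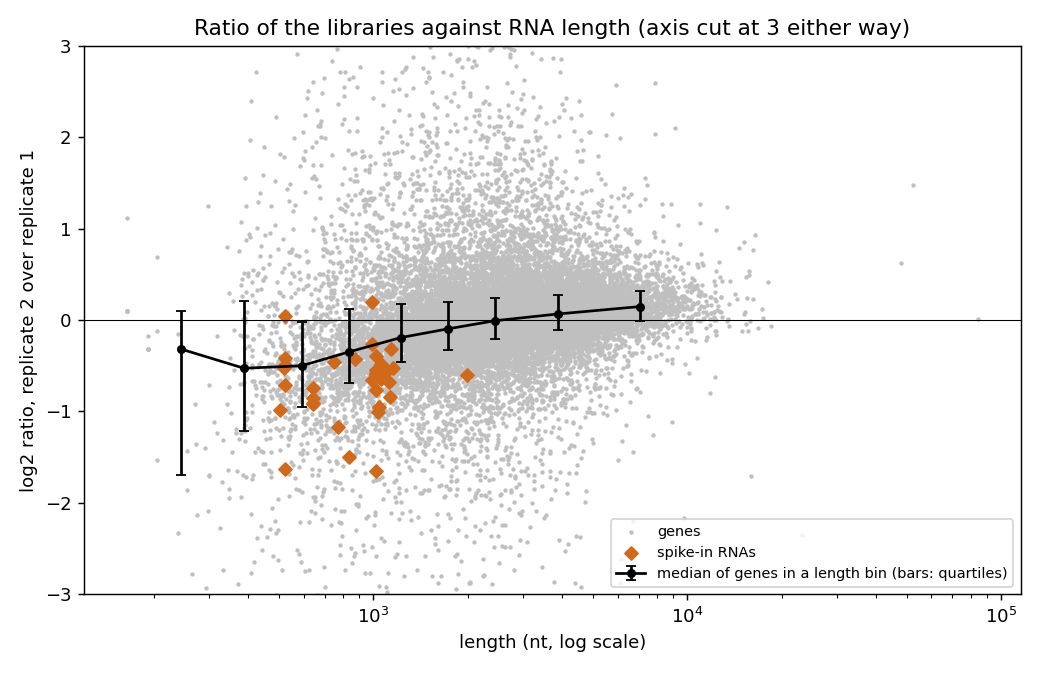
Log2 ratio (replicate 2 over replicate 1) by length in nt on a log axis, with grey points for genes, diamonds for spike-ins, black points and bars for the median and quartiles of genes in each length bin, and ratios beyond 3 either way not drawn. Medians run from -0.53 at 300 to 500 nt to 0.15 above 5000 nt.

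Between the replicates, log2(coding TPM + 0.1) correlated with Pearson's r of 0.961 and Spearman's rho of 0.979 across the 17544 genes, which are not independent replicates. The biological coefficient of variation was 0.256 over all these genes and 0.212 over protein-coding genes, and 89% of genes lay within 2-fold of each other. The external ERCC spike-ins, synthetic RNAs added to each sample, took 1.38% (95% Wilson interval 1.375 to 1.381%) of counts in replicate 1 and 0.949% (95% Wilson interval 0.9467 to 0.9513%) in replicate 2, a mean of 1.16 ± 0.304%. Of 96 spike-ins 64 were detected in both libraries, and the 36 with a mean of at least 100 counts had a median log2 ratio of -0.61.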

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

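No test in this part was chosen after the result was seen, and no explanation was weighed here. Fragments assigned to phiX174, the bacteriophage genome commonly sequenced as a control, lay outside the analysis of mouse genes and stood above the limit that a count of 0 allows, at 0.34% of expected counts in replicate 1 and 0.287% in replicate 2.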

How the results depend on the processing

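The alternatives with protein-coding genes alone, coding TPM and the length and GC trend removed were chosen after the results were seen, and all others before. Of 44 alternative values of the main results, 30 stayed within their tolerance and 14 moved, the tolerance being 1.5 times for counts of genes, lists or pairs, 1 SD for the regional difference and spike-in share and 1% for the coefficient of variation. Counts within it still reached 14936 detected genes in coding TPM against 11151 and 2565 differing genes without a filter against 1808. At 5 TPM, 5454 genes were detected, as a higher threshold must give fewer. The coefficient of variation was 0.278 with library totals, 0.282 without a filter, 0.189 at 100 counts, 0.25 with posterior mean counts and 0.212 over protein-coding genes. Differing genes numbered 380 at 100 counts and 1101 among protein-coding genes, where fewer genes were tested, and 3432 at 1.5-fold, a looser threshold. The telencephalic minus hindbrain median was 2.28 with a pseudocount of 1 TPM, 8.57 with 0.01, 6.31 in FPKM, 3.35 with members of at least 0.1 TPM and 7.78 in coding TPM, always above 0. The midbrain and hindbrain list reversed to 0.87 at 100 counts, where 3 members were left. For the changes in the coefficient of variation the cause was not tested. Among list medians 162 alternatives kept direction and side of the threshold, 8 lost the threshold, 1 gained it and 20 changed sign, 19 of them for lists inside the random range in the main comparison. Library totals add about 0.196 to every ratio and barely move the place among random lists, so their changes of sign say nothing about the lists. After a change of sign the medians were, with library totals, 0.00275 (subplate), 0.15 (pan-neuronal), 0.18 (myelinating), 0.0818 (microglial), 0.18 (Y-linked), 0.17 (mitochondrial), 0.0138 (histone) and 0.0569 (hypoxia); without the member of largest ratio, -0.0631 (deep-layer), -0.00643 (glutamatergic), 0.0912 (myelinating), 0.0257 (Y-linked), -0.00681 (immediate early) and 0.0378 (mitochondrial); and with the length and GC trend removed, -0.11 (deep-layer), -0.0758 (glutamatergic), 0.14 (microglial), 0.34 (mitochondrial) and 0.32 (histone), the histone and mitochondrial lists then lying above the range. Of the ratios of named genes 70 kept both and 7, all under the error with the posterior SD, lost the threshold. Leaving out each replicate gave 11209 to 12734 detected genes, 4.71 to 5.86 for the regional difference and 0.949 to 1.38% spike-ins. With n = 2 libraries each value lies within 1 SD of the mean in any case. The regional difference and spike-in share were thus bound to stay within tolerance here, which says nothing about stability. Leaving out a replicate could give no value for the coefficient of variation, differing genes, list shifts or shared isoforms, which need both libraries. Depth limits the genes with few counts, such as the Hox genes and Pitx3.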

Other observations

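The tests of length, on effective length and on spike-ins, were chosen after the result was seen, and the lists of hypothalamic, osteoblast, leptomeningeal and midbrain dopamine genes were chosen after the extreme ratios were seen, although the outcomes to be tested on them were written before. Genes named in the next paragraph were chosen after their values were seen.

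Newborn forebrain held transcripts of hypothalamic neuropeptides and of bone, cartilage and muscle. Avp, the vasopressin gene, had 86.6 ± 2.88 coding TPM (n = 2 libraries), Pmch, which encodes melanin-concentrating hormone, 19.8 ± 5.16, Trh, which encodes thyrotropin-releasing hormone, 17.5 ± 5.28 and Agrp, a feeding peptide gene, 0.815 ± 0.832. Ptgds, a prostaglandin synthase of the leptomeninges, stood at 1445 ± 303, Slc6a13 at 41.6 ± 3.63 and Foxd1 at 3.24 ± 0.219. Of 273 protein-coding genes with a posterior SD under 5% of the count and a mean of at least 100 counts that differed between the libraries, 148 were higher and 125 lower in replicate 2. The higher ones included Col1a1 at 2.57 (SE 0.027), the cartilage collagen Col2a1 at 1.86 (SE 0.063), the phosphate regulator Phex at 2.40 (SE 0.20) and Aspn at 2.12 (SE 0.19) on the log2 scale, and the midbrain factor Lmx1a at 1.97 (SE 0.18). The lower ones included the actin-binding Tmsb10 at -2.52 (SE 0.021), the ribosomal Rps13 at -1.86 (SE 0.030), Rpl38 at -1.65 (SE 0.033) and Rpl35 at -1.68 (SE 0.041), the myosin Myh8 at -2.61 (SE 0.22) and the dopamine transporter Slc6a3 at -1.81 (SE 0.15). Another myosin, Myh6, was among the higher ones at 2.25 (SE 0.29). With the length and GC trend removed, Tmsb10 was at -1.97, Rps13 at -1.29, Rpl35 at -1.36 and Rpl38 at -0.95, the last under 2-fold.

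Short transcripts were lower in replicate 2. A difference in fragment length that the effective length already covers is argued against, because the log2 ratio of TPM, which includes it, still rose with length across genes (Spearman's rho 0.246, 95% bootstrap interval 0.231 to 0.26). Loss of short molecules after the spike-ins were added stays open, since their slope was 0.0967 log2 per doubling of length (95% bootstrap interval -0.17 to 0.38, two-sided permutation p = 0.499, n = 36 spike-ins of 505 to 1994 nt) against 0.289 for genes of these lengths. That interval holds both 0 and the slope of the genes. No biological explanation was tested, because the design has 1 group.

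Diencephalic factors were higher in replicate 2. The length and GC trend is argued against as the whole source, since with it removed the median was 1.09 against a range of -0.27 to 0.43 for matched random lists. More hypothalamic tissue in that isolate is a candidate explanation that stays open, because a separate list of 10 neuropeptide and regulator genes lay inside the range, at percentile 81.8 with a median of 0.27 and 6 members higher, and at percentile 96.4 with a median of 0.60 once the length and GC trend was removed. With the called genes that prompted the list put back it lay at percentile 100, which is no independent evidence. No biological explanation from the design was tested.

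Meningeal fibroblast genes were higher in replicate 2. The length and GC trend is argued against as the whole source, with a median of 0.88 after its removal against a range of -0.23 to 0.14. More skull bone in the isolate may contribute, as a separate osteoblast list had a median of 0.82 at percentile 99.6, with ratios above 0 for 7 of 7 members, Col5a2 (0.96, SE 0.036), Sp7 (0.95, SE 0.23) and Postn (0.82, SE 0.052) under 2-fold and Alpl (0.11, SE 0.091) nearer 0, and only Bglap2, of bone matrix, past the test at 0 and 43 counts (at least 11.8-fold), while Mepe had 0 and 4. More leptomeninges may contribute too, as a list of 8 genes apart from bone had a median of 0.28 at percentile 98.6, but its 95% bootstrap interval of -0.0648 to 0.49 holds 0 and no member reached 2-fold, Slc22a6, Slc13a4, Ogn and Aldh1a2 the highest. Both stay open together, Col5a2, Postn and Alpl are also expressed outside bone, and no biological explanation from the design was tested.

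The hypothesis that the replicate 1 isolate held more midbrain, drawn from the lower En1, En2 and Pax7 in replicate 2, was tested on a separate list of midbrain dopamine neuron genes. Written beforehand, the predicted outcome was a list at the low end of the random lists, and a list above their middle was to count against it. The called Slc6a3 was lower and had prompted the list. With Slc6a3 included, the 8 tested members had a median of 0.51 (95% bootstrap interval -1.79 to 0.94). They lay at percentile 97.2, inside the range of random lists. Without Slc6a3 the list lay above that range, at percentile 98.1 with 6 of 7 members higher in replicate 2 and a median of 0.64. By the rule written beforehand, both places count against the hypothesis. It is left open here because the interval holds 0 and members went both ways, a criterion that was not written beforehand. Foxa1 (7 and 85 counts), Th at 0.80 (SE 0.11), Ddc at 0.64 (SE 0.11) and Slc10a4 at 0.94 (SE 0.11) were higher, whereas Slc6a3 at -1.81 (SE 0.15) and Chrna6 at -1.79 (SE 0.45) passed the test as lower and Pitx3 had 8 and 0 counts. Th and Ddc are also expressed by other monoaminergic neurons, so the list speaks for these cells as a group only.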
